A study of Saccharomyces cerevisiae BY4741 with 2 samples.

How the data were processed

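RNA was measured by strand-specific sequencing of ribosome-depleted total RNA from 2 haploid strains of the budding yeast Saccharomyces cerevisiae. One was a wild-type reference strain and the other carried a deletion of DBP2, which encodes an RNA helicase of the DEAD-box family. The strains differed in more than DBP2, since the labels give a lysine auxotrophy for the deletion strain only. Per the labels' protocols, cultures grew in rich medium with glucose to mid-log phase at a single temperature. Ribosomal RNA was removed in repeated rounds with a hybridisation kit, and libraries were made with a SOLiD total RNA kit. The labels list 2 replicates per strain, but the deposited data have 1 sample and 1 value column per strain.

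The deposited values were taken as FPKM (fragments per kilobase of transcript, scaled for library size). The reasons were that the submitters' processing notes name Cuffdiff 2.1.1, and that the values are not whole numbers and sum to more than CPM or TPM could. The notes also name the genome build sacCer3. How Cuffdiff combined the replicates and how it scaled the libraries to each other are not given in the sources used here. The aligner, the gene annotation and the use of strand in assigning reads to genes are not given either. No read counts or depths are given, and low values did not fall on steps that would give whole reads. The depth is therefore unknown, and no counting interval or detection limit was computed.

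Each file has 3146 rows with a gene name and a value, in the same order for both strains. There are 2809 distinct names, of which 306 stand on more than 1 row (276 on 2 rows, 29 on 3 and 1 on 4). How the rows of a name differ is not stated, so these 643 rows were kept out of the main comparison. A further 7 rows name several genes and were also left out. Names were matched to the RefSeq annotation of assembly R64, the assembly that the build name sacCer3 refers to, through symbols, locus tags and unambiguous synonyms, which placed 2454 names. Coordinates below are 1-based R64 positions from that annotation. The rows matched 2369 of its 6021 protein-coding genes. On 8 chromosomes (I, III, VI, VIII, IX, X, XI and XIV) between 78.6% and 96.8% of the coding genes were matched. On the other 8 nuclear chromosomes the share was 2.09% to 47.6%, and it was 52.5% within 50 kb of a chromosome end against 10.4% elsewhere. Genes outside this set were not analysed here, among them the genotype markers URA3, HIS3, MET17, LYS2 and TRP1.

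A value of exactly 0 can be a failed estimate in Cuffdiff output, and abundant genes are among those listed at 0 (the pyruvate kinase gene CDC19 is listed at 31167 FPKM in wild type and at 0 in the deletion strain). Of the 2496 genes on a single row, 132 were listed at 0 in both strains, 56 in wild type only and 15 in the deletion strain only. No ratio was formed for these. The genes compared were those on 1 row, above 0 in both strains and with a mean of at least 1 FPKM, 2211 in all, of which 1986 are protein-coding in the reference. For each, the log2 of (dbp2 deletion + 1) / (wild type + 1) was computed, with a pseudocount of 1. This scale understates the change of low genes. A fold given below is the plain ratio of the 2 deposited values. No scaling was added to the deposited values.

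With 1 value per strain there is no estimate of the spread between replicates, so no test, standard error or p-value was computed for any gene, and no difference below has a replicate check. Genes were counted by a size limit of 2-fold on the log2 scale with the pseudocount. The 37 gene lists were fixed before the data were examined. For a list with at least 4 genes compared, its median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn to match it over 20 bins of mean FPKM. That percentile describes these 2 samples and is not a p-value. Named genes were fixed by rule before the data were examined: DBP2, the genotype markers, the 12 largest and 12 smallest log2 ratios among genes with a mean of at least 10 FPKM (transfer and ribosomal RNAs left out), and up to 4 members of each list by size of the log2 ratio. Restricting the rule to genes on 1 row and above 0 in both strains was decided after the files were seen, and any other gene named was chosen after its values were seen. Of the lysine synthesis list, single genes are given and the list median is not reported here. All computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for plots.

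The procedure was tested on simulated data for this comparison with 2211 genes and an assumed log2 error of SD 0.4 per strain. With 1 value per strain that error could not be estimated from the data. Of 200 genes changed by 4-fold, 91.0% passed the 2-fold limit in the right direction, while 6.36% of unchanged genes also passed it. Both shares follow from the assumed error and are not error rates of the measured data. Of 200 random lists of 10 genes drawn from the measured log2 ratios with no shift, 5.50% lay outside the central range between the 2.5th percentile and its upper counterpart, and 96.5% of such lists shifted by 1 on the log2 scale lay above it. The share without a shift is near its set value by construction, and shorter lists were not simulated. Alternatives fixed before the data were examined were other pseudocounts, other filters, other scalings, other size limits and the removal of near-identical genes. Counting every row, using the highest row of each name, keeping genes listed at 0, drawing random lists outside the list and restricting to protein-coding genes were added afterwards.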

Results

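The data compared steady-state RNA in a dbp2 deletion strain with RNA in a wild-type reference strain, with 1 deposited FPKM value per row and strain, so no difference below has a replicate check. The deposited values summed to 5210210 FPKM over all rows in wild type and 1724410 FPKM in the deletion strain, and the 10 highest rows held 79.3% and 56.9% of these sums. Over the 2211 genes compared the medians were close, at 87.5 FPKM in wild type and 87.9 FPKM in the deletion strain. Log2 values of both strains correlated with Pearson's r = 0.94 across genes, which are not independent replicates.

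The first question was whether the deleted gene was missing. DBP2 (YNL112W) lies on chromosome XIV at 413639 to 416281 and has 2 exons separated by an intron of 1002 bp. It stands on 3 rows. The highest row was 1539.7 FPKM in wild type and 2.52 FPKM in the deletion strain, a 611-fold lower value. Another row was 348 FPKM against 3.70 FPKM, and the remaining row was low in both strains, at 5.62 FPKM and 3.33 FPKM. LEU2, a leucine synthesis gene that the labels give as deleted in both strains, was at 1.69 FPKM in wild type and 0.54 FPKM in the deletion strain. It was the sole genotype marker besides DBP2 in the rows analysed. Mating-type genes were examined next. The a-pheromone receptor gene STE2 was at 433 FPKM in both, and the a-factor transporter gene STE6 was at 462 FPKM and 357 FPKM. The alpha-cell genes MATALPHA1 and STE3 did not exceed 4.10 FPKM in either strain, while the alpha-agglutinin gene SAG1 stood on 2 rows, at 33.8 FPKM in wild type and 20.8 FPKM in the deletion strain and at 5.18 FPKM and 11.2 FPKM. BAR1, an a-cell protease gene, was 141 FPKM in wild type and 32.2 FPKM in the deletion strain. The list of a-cell genes had 5 members compared and a median log2 ratio of -0.37, at the 37.2th percentile of level-matched random lists, and a median of 0.10 when both strains were set to the same protein-coding sum.

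Against wild type, 196 genes (8.86%) were at least 2-fold higher in the deletion strain, 241 (10.9%) were at least 2-fold lower and 1774 lay in between. The largest ratio belonged to HSP12, a small membrane-associated heat shock gene on chromosome VI at 107256 to 107585, with 251 FPKM in wild type and 17124 FPKM in the deletion strain (68.2-fold). NCA3 on chromosome X (193860 to 194873) followed with 14.2 FPKM against 463 FPKM, and RTC3 on chromosome VIII (280820 to 281155) with 32.7 FPKM against 818 FPKM. At the other end stood PHO12, an acid phosphatase gene on chromosome VIII at 552099 to 553502, which was 105.1 FPKM in wild type and 2.13 FPKM in the deletion strain (49.3-fold lower). The tryptophan permease gene TAT2 on chromosome XV (286172 to 287950) was 13.6-fold lower and ANB1, one of a pair of similar eIF5A genes, on chromosome X (524908 to 525381) was 10.5-fold lower. Each of these 6 genes has a single exon in the annotation. The other genes among the 12 largest ratios were HSP30, DDR2, YGP1, RRT5, PIR3, ARO9 (an aromatic aminotransferase, 8.89-fold), RIM4 (a meiotic RNA-binding protein, 10.5-fold), TSL1 and RSF2 (a zinc-finger regulator, 7.06-fold). Those among the 12 smallest were PHO11, SPL2, the small nucleolar RNA gene SNR71 (8.41-fold), HIS4, ENB1, YOL083C-A, PHO89, URA1 (dihydroorotate dehydrogenase, 6.13-fold) and VTC4. The split between higher and lower genes depended on the scaling. With both strains set to the same sum over protein-coding genes, 441 genes were at least 2-fold higher and 101 at least 2-fold lower. That scaling raised the median log2 ratio by 0.46. The deposited scaling also showed a trend with level: the median log2 ratio was 0.10 in the lowest of 5 groups of genes by mean FPKM and -0.48 in the highest.

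**Figure D1:**
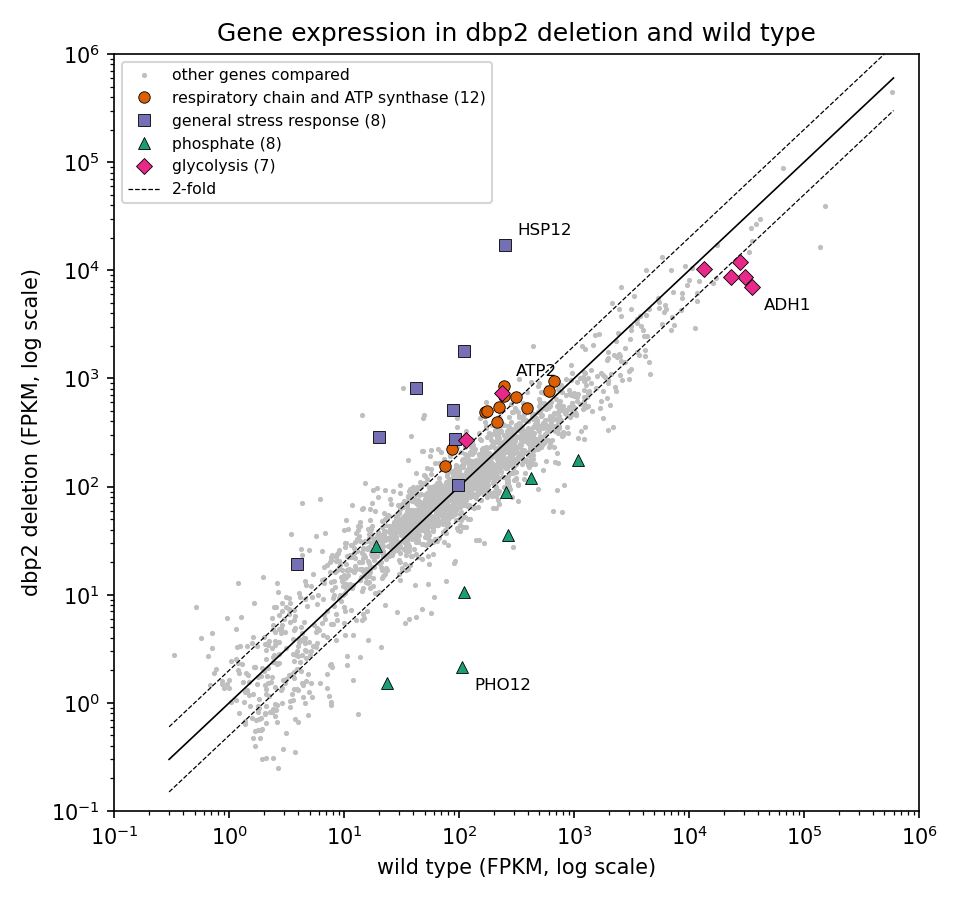
Each point is 1 of the 2211 genes compared, with its FPKM in wild type on the x axis and in the dbp2 deletion strain on the y axis (both log scales); 4 gene lists are coloured, the solid line marks equal values and the dashed lines a 2-fold difference. All 12 respiratory chain genes lie above the line of equality, 7 of 8 phosphate genes lie below the lower dashed line, and HSP12 stands at 251 FPKM in wild type and 17124 FPKM in the deletion strain.

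The general stress genes compared were higher in the deletion strain. Of the 24 genes on the list 9 were in the rows, and GRE1, on 2 rows, was not compared. All 8 members compared had higher values and 7 were at least 2-fold higher, as deposited and with equal protein-coding sums, with a median log2 ratio of 3.16, above all 10000 random lists. Besides HSP12, the plasma membrane heat shock gene HSP30 was 42.3 FPKM in wild type and 823 FPKM in the deletion strain, DDR2 was 110.2 FPKM and 1801 FPKM, and the secreted glycoprotein gene YGP1 was 19.95 FPKM and 286 FPKM. Trehalose and glycogen genes were split. TSL1, a subunit of trehalose synthase, was 7.66-fold higher and the glycogenin genes GLG1 and GLG2 were 2.49-fold and 2.67-fold higher, whereas the phosphoglucomutase gene PGM1 was 3.99-fold lower. The median of the 5 members was 1.25, at the 99.4th percentile. Cell wall genes had a median of 0.85 (99.9th percentile over 8 members compared), with PIR3 12.5-fold, HSP150 2.84-fold, CWP2 2.73-fold and CWP1 2.04-fold higher. This list depended on the rows used, since its median was 0.26 when all rows of repeated names were counted. Cytosolic and organellar chaperones that respond to heat shock did not share the direction of the stress genes. As deposited, all 7 members were lower (6 of 7 with equal protein-coding sums), including HSP82 at 1921 FPKM and 665 FPKM, HSP10 at 399 FPKM and 157 FPKM, KAR2 at 1216 FPKM and 586 FPKM and SSA1 at 769 FPKM and 414 FPKM. Their median of -0.89 lay at the 10.4th percentile and so was not apart from genes of similar level. HSP82 and SSA1 have close paralogs that can share reads.

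The respiratory chain genes compared were higher in the deletion strain. Of 7 glycolysis genes, 5 were lower as deposited and 4 with equal protein-coding sums. All 12 respiratory chain and ATP synthase genes compared had higher values under every scaling used, 8 of them by at least 2-fold as deposited, and the median log2 ratio of 1.19 lay above all 10000 random lists. Of the 34 genes on the list 13 were in the rows, and NDI1, on 2 rows, was not compared. Its rows went opposite ways, at 51.7 FPKM in wild type and 19.8 FPKM in the deletion strain, and at 29.1 FPKM and 72.6 FPKM. The ATP synthase beta subunit gene ATP2 was 245 FPKM in wild type and 848 FPKM in the deletion strain. The iso-1-cytochrome c gene CYC1 was 167 FPKM and 487 FPKM, the cytochrome oxidase gene COX5B was 176 FPKM and 496 FPKM, and ATP7 was 248 FPKM and 688 FPKM. The TCA cycle list had a median of 0.04 over 6 members (81.3th percentile), with SDH3 at 2.03-fold and KGD1 at 1.52-fold higher, and IDH1 and MDH1 at 0.81 and 0.92 of wild type, though all 6 were higher with equal protein-coding sums. The 5 genes of the mitochondrial genome in the rows (ATP6, ATP8, COX3, OLI1 and VAR1) were listed at 0 in both strains. In glycolysis, 4 of 7 members were at least 2-fold lower (2 with equal protein-coding sums) and 2 at least 2-fold higher. The alcohol dehydrogenase gene ADH1 was 34928 FPKM in wild type and 7047 FPKM in the deletion strain, the phosphoglycerate kinase gene PGK1 was 30793 FPKM and 8627 FPKM, and the enolase gene ENO2 was 23068 FPKM and 8577 FPKM. The glucokinase gene GLK1 was 235 FPKM and 731 FPKM. The median of -1.21 lay at the 2.56th percentile, just inside the limit of 2.5, and was -0.74 with equal protein-coding sums. These abundant genes are part of the protein-coding sums, so their own lower values raise the scaled ratios. The scaled values are therefore not an independent check of this list. ENO2 has a near-identical paralog, and the median of the other 6 members was -0.81. The abundant pyruvate kinase gene CDC19 was listed at 31167 FPKM in wild type and at 0 in the deletion strain, for which no ratio is given.

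Dbp2 has been linked to glucose-dependent gene expression, so transporters and glucose-repressed genes were examined separately. Of 5 hexose transport and sensing genes compared, the transporter genes HXT4 and HXT1 were 4.09-fold and 2.64-fold higher, at 80.5 FPKM and 299 FPKM in the deletion strain. HXT17 was listed at 4565 FPKM in wild type and 1106 FPKM, and HXT14 at 2.92 FPKM and 1.61 FPKM. HXT17 has a near-identical copy that can share its reads, and the list's median moved from -0.27 (39.7th percentile) to 0.56 without it and to 0.19 with equal protein-coding sums. Genes of gluconeogenesis and growth on non-fermentable carbon had a median of 0.40 over 6 members (88.1th percentile) and of 0.85 with equal protein-coding sums, where 3 were at least 2-fold higher and 0 lower in place of 0 and 1. The aldehyde dehydrogenase gene ALD6 was 2.42-fold lower, and ATO2, MDH2 and ACS1 were 1.69-fold, 1.54-fold and 1.56-fold higher. Another 6 members stood on several rows and were not compared. PCK1 was 3.69-fold and 2.13-fold higher on its rows, SFC1 8.96-fold and 1.71-fold and MLS1 1.24-fold and 1.01-fold, all at or below 21.1 FPKM. GUT2, SIP4 and JEN1 had rows going both ways. Other sugar-use genes gave 3 values, with MAL31 at 2.03-fold, MAL33 at 1.17-fold and the invertase gene SUC2 at 0.80 of wild type. The galactose list had no member on a single row. GAL4, the activator of galactose genes, was on 2 rows, at 29.9 FPKM and 37.6 FPKM for the higher one.

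Most of the phosphate starvation genes compared were lower in the deletion strain. Of the 17 genes on the list 8 were in the rows. Of 8 members compared, 7 were at least 2-fold lower, as deposited and with equal protein-coding sums, and the median log2 ratio of -2.74 lay below all 10000 random lists. Besides PHO12, the acid phosphatase gene PHO11 was 23.7 FPKM in wild type and 1.52 FPKM in the deletion strain. The regulator SPL2 was 111 FPKM and 10.6 FPKM, and the sodium-phosphate cotransporter gene PHO89 was 268 FPKM and 35.6 FPKM. The polyphosphate polymerase gene VTC4 was 6.07-fold lower, and GIT1 was the member with a higher value, at 1.47-fold. PHO11 and PHO12 are near-identical and can share reads. The other 6 members had a median of -2.19. Iron and copper uptake had a median of -1.32 over 4 members, at the 0.23th percentile, with 3 members lower as deposited and 2 with equal protein-coding sums. The siderophore transporter genes ENB1 and ARN2 were 7.69-fold and 5.12-fold lower, ARN1 was at 0.82 of wild type, and the iron-sulfur scaffold gene ISU1 was 2.04-fold higher. Zinc genes gave 3 values within 1.33-fold of wild type (ZRT3, ZAP1 and IZH2).

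Amino acid synthesis genes had a lower median. In the general list 7 of 14 members were at least 2-fold lower and 2 at least 2-fold higher (3 and 3 with equal protein-coding sums), with a median of -0.69 at the 2.12th percentile. With equal protein-coding sums the median was -0.23, with 7 members higher and 7 lower. The histidine synthesis gene HIS4 was 810 FPKM in wild type and 103 FPKM in the deletion strain, the arginine genes ARG1 and ARG4 were 148 FPKM and 32.3 FPKM, and 325 FPKM and 104 FPKM, and the serine gene SER33 was 390.5 FPKM and 167 FPKM. Among lysine synthesis genes LYS9 and LYS12 were 4.46-fold and 2.21-fold lower and LYS1 was 2.57-fold higher. The labels give a lysine auxotrophy for the deletion strain alone. Methionine and sulfur genes had a median of -0.30 over 14 members (5.61th percentile) and of 0.17 with equal protein-coding sums. MET14 was 3.25-fold lower and MET4, the activator of the pathway, was 2.54-fold higher. SAM3 and MET2 were 2.13-fold and 2.01-fold lower. Sterol synthesis genes had a median of -0.54 over 8 members (32.8th percentile), -0.07 with equal protein-coding sums, with ERG13 2.15-fold, ERG24 1.93-fold, ERG20 1.66-fold and MVD1 1.52-fold lower. Thiamine and vitamin B6 genes had a median of 0.48 over the 5 members compared (89.5th percentile), of which THI12, SNO3, SNO2 and SNZ2 were at or below 4.89 FPKM.

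Ribosomal and RNA processing genes did not stand apart from genes of similar level. Of 40 cytosolic ribosomal protein genes, 31 were lower (21 with equal protein-coding sums) and 10 at least 2-fold lower (4 with equal protein-coding sums, where 2 were at least 2-fold higher), among them RPL9B (4.17-fold), RPL8A (3.45-fold), RPS6A (3.06-fold) and RPL1A (2.82-fold). Their median of -0.51 lay at the 52.2th percentile. Most have a near-identical copy that can share reads, and the median of the 6 members without one was -0.01. Mitochondrial ribosomal protein genes had a median of -0.41 over 25 members (4.88th percentile), with RSM19, MRPL6, MRPL32 and MRP51 between 2.43-fold and 2.84-fold lower, and a median of 0.05 with equal protein-coding sums. Ribosome biogenesis genes were mixed. Of 21 members, 10 had higher and 11 lower values as deposited (18 and 3 with equal protein-coding sums), with IMP3 2.14-fold and NOP15 1.64-fold higher and GAR1 and KRR1 at 0.51 and 0.61 of wild type. Their median was -0.16 (87.1th percentile), and 0.31 with equal protein-coding sums. RNA polymerase I and III genes had a median of -0.12 over 9 members (68.5th percentile), and of 0.35 with equal protein-coding sums, with RPC17 and RPC34 at 0.50 and 0.53 of wild type, RPC19, an immediate neighbour of DBP2, at 1.85-fold and RPC31 at 0.61 of wild type.

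RNA helicases and RNA-binding factors were examined next. The 9 DEAD-box genes other than DBP2 had a median of -0.16 (46.5th percentile), and of 0.31 with equal protein-coding sums. DBP6 was 3.01-fold higher, TIF1 and DBP1 were 2.08-fold and 2.03-fold lower and DBP7 was at 0.68 of wild type. TIF1 has a near-identical copy, TIF2. Among mRNA packaging and export genes NAB3 was 2.42-fold, MEX67 1.66-fold and MTR2 1.57-fold higher and THP2 2.13-fold lower, with a median of 0.04 over 9 members (73.3th percentile) and of 0.51 with equal protein-coding sums, where 3 were at least 2-fold higher and 0 lower in place of 1 and 1. None of 16 RNA decay and surveillance genes reached 2-fold as deposited, and 2 did with equal protein-coding sums. Their median was -0.03 (64.9th percentile) and 0.43 with equal protein-coding sums, with MTR4 at 0.59 of wild type, NRD1 and CCR4 at 1.60-fold and 1.58-fold, and TRF5 at 0.70. Small nucleolar and nuclear RNAs had a median of -0.51 over 22 members (62.2th percentile) and of -0.04 with equal protein-coding sums, where 3 were at least 2-fold higher and 3 lower in place of 1 and 7. SNR71 was 137788 FPKM in wild type and 16393 FPKM in the deletion strain, SNR87 was 151952 FPKM and 39614 FPKM, SNR49 was 3.86-fold lower and SNR17B 2.76-fold lower. FPKM of RNAs this short depend strongly on the length correction. The RNase MRP RNA gene NME1, the 1 member of the structural RNA list compared, was at 0.58 of wild type. Of 26 transfer RNA genes, 5 were at least 2-fold higher and 5 at least 2-fold lower (median -0.37, 18.7th percentile, and 0.08 with equal protein-coding sums), and near-identical copies can share their reads.

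The remaining lists gave no median outside the random range. Proteasome genes had a median of -0.12 over 10 members (93.2th percentile), 0.35 with equal protein-coding sums, with RPN1 at 0.54, RPT1 at 0.68 and RPN2 at 0.69 of wild type and PRE4 at 323 FPKM and 486 FPKM. Mating pathway genes had a median of -0.29 over 6 members (23.6th percentile), 0.14 with equal protein-coding sums, with FAR1 2.35-fold and FUS1 2.24-fold lower, STE12 1.78-fold higher and AGA1 at 0.67 of wild type. Meiosis genes had a median of -0.34 over 5 members (20.1th percentile), 0.01 with equal protein-coding sums. Among them DMC1 was 4.49-fold and HOP1 3.61-fold lower, while NDT80 was 2.89-fold higher and IME1 was 3.07 FPKM and 4.54 FPKM. The histone genes HHF2, HHT2 and HTZ1 were at 0.56, 0.76 and 0.65 of wild type. In total 8 of the 29 lists with a percentile lay outside the central range that leaves 2.5% of random lists on each side, 4 on each side. Lists of unrelated genes would give 1.45 outside on average. Genes of 1 list can move together within a sample, so setting 8 beside 1.45 is not a test.

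**Figure D2:**
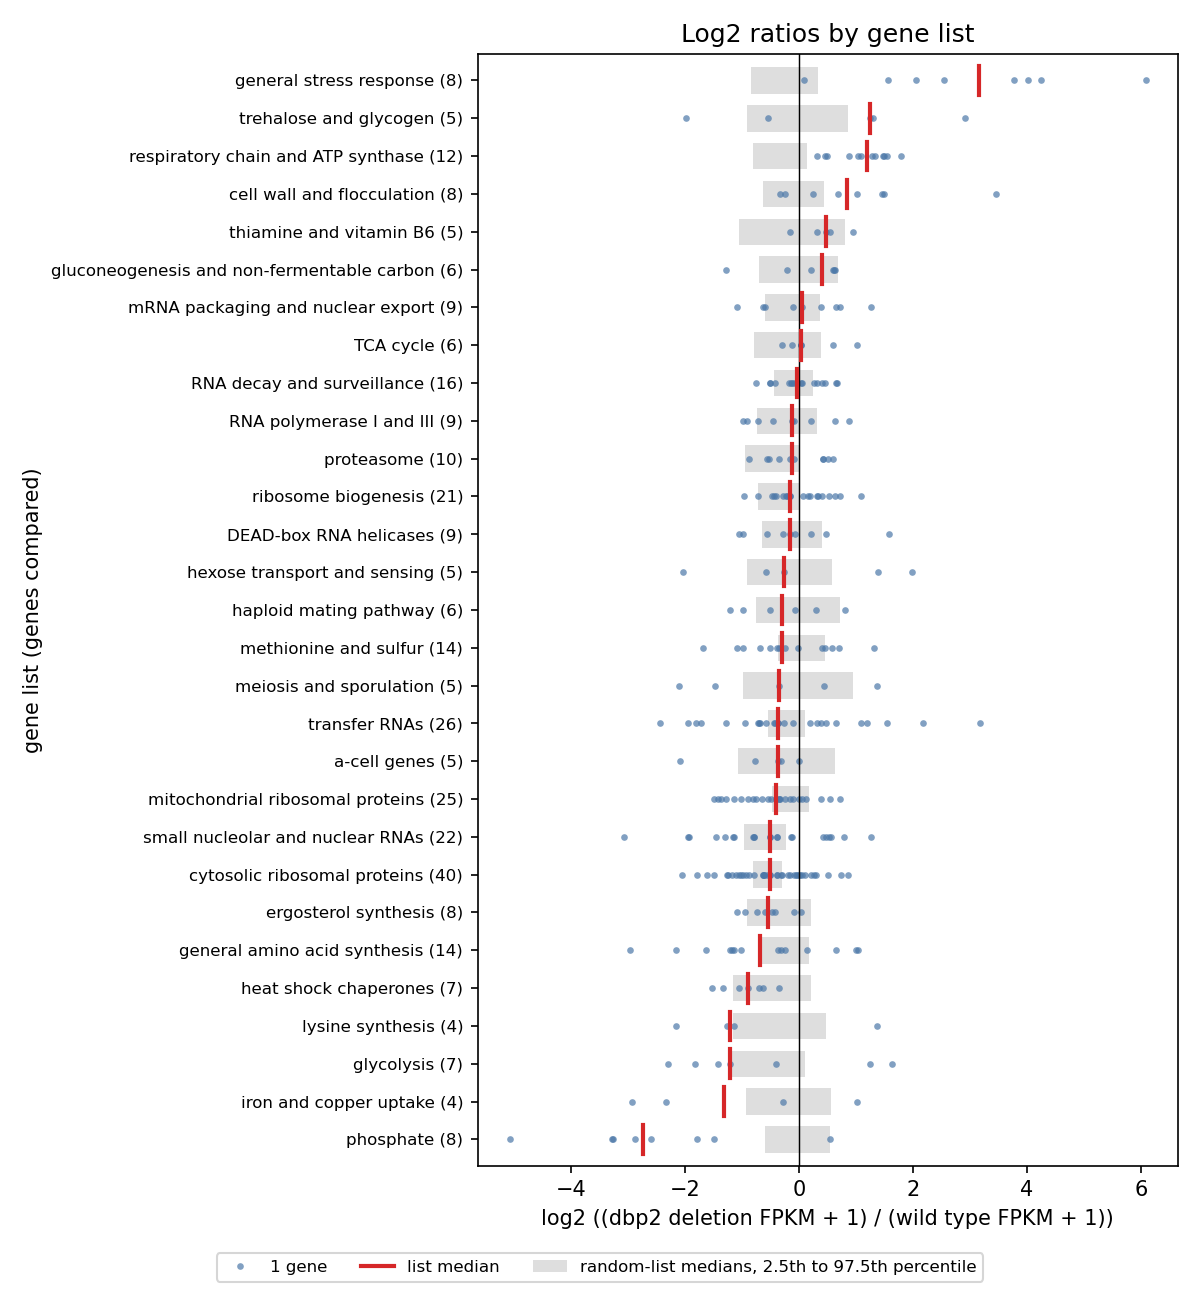
Log2 ratios of dbp2 deletion to wild type (x axis, pseudocount 1) for the 29 gene lists with at least 4 genes compared (y axis, number of genes in brackets). Points are genes, red bars list medians and grey bars the range of the medians of 10000 level-matched random lists without the outer 2.5% on each side; the stress (3.16) and respiratory chain (1.19) medians lie to the right of their grey bars and the phosphate median (-2.74) to the left.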

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

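The rank correlation of the rows and the share of matching changes were set as tests before their results were seen, and the Pearson values were not set in advance.

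Rows of repeated gene names, which the counts of genes and the list medians as first given above leave out, held 99 rows at least 2-fold higher in the deletion strain than in wild type and 106 at least 2-fold lower among 621 rows above the same limits. These shares, 15.9% and 17.1%, stand beside 8.86% and 10.9% of the genes on a single row, without matching on level. The rows of one name often went opposite ways. HXK1, a hexokinase gene, had a row at 25.4 FPKM in wild type and 245 FPKM in the deletion strain and another at 74.5 FPKM and 11.6 FPKM. MSN4, a stress-response activator, had rows at 9.28 FPKM and 79.6 FPKM, and at 10.4 FPKM and 0.63 FPKM. HAP4, the activator of respiratory genes, had rows at 13.5 FPKM and 49.0 FPKM, and at 15.7 FPKM and 5.31 FPKM. The succinate dehydrogenase gene SDH1 had rows at 18.6 FPKM and 72.5 FPKM, and at 8.80 FPKM and 0.90 FPKM. These names were chosen after their values were seen.

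Over the 258 names with both of 2 rows measured, the log2 ratios of the higher and the lower row were weakly and negatively correlated across genes, which are not independent replicates (Spearman's rho = -0.16, two-sided permutation p = 0.0115; Pearson's r = -0.14, permutation p = 0.0289, and -0.11 without the 2 names farthest from the median). Rows went opposite ways in 55.8% of names, where independent rows would give 51.8%. The rank correlation argues against random pairing alone, but the effect is small. Both rows were past 2-fold in opposite directions for 24 names, a count with no chance value beside it that decides nothing here. What distinguishes the rows of a name was not tested, since the files give them no strand or position. Splitting of the reads of 1 transcript between 2 rows stays open. The changes in FPKM were within 2-fold of each other in 18.1% of opposite-moving names, against 21.1% of names moving together. The limit set beforehand counted a share this low against splitting. That limit was not applied, because the lengths of the rows are unknown, so FPKM cannot be added across them.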

How the results depend on the processing

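The alternatives that count every row, use the highest row of each name, keep genes listed at 0, draw random lists outside the list or take protein-coding genes alone were chosen only after the data were seen. No paired analysis was possible because each strain has 1 value column, and for the same reason no replicate could be left out. The fits planned for replicate columns or read counts were not run. The counts of 196 higher and 241 lower genes became 412 and 524 with a 1.5-fold limit, 36 and 40 with a 4-fold limit and 441 and 101 with the same sum over protein-coding genes, where the share of higher genes among those past the limit went from 44.9% to 81.4%. Counting every row gave 295 higher rows, 99 of them rows of repeated names. The other 17 alternatives for the counts stayed within 1.5 times. Of the lists outside the random range, cell wall moved to 0.26 with every row counted, and with the highest row of each name general stress moved to 3.78 and iron and copper uptake to -1.99. In these, repeated-name members entered. The other 77 alternatives for those 8 lists moved the median by less than 1.5-fold, and none of these 8 turned its sign. Some of these alternatives could not have moved a median that far. Removing near-identical genes took no member out of these 8 lists. Centring on the median and equal protein-coding sums shift all genes by nearly the same amount, which was under 1.5-fold. With a pseudocount of 5 the 2 high DBP2 rows gave log2 ratios of -7.68 and -5.34 in place of -8.77 and -6.22. Among the other named genes 5 values moved by more than 1.5-fold and 219 did not, and among the other lists 7 moved and 260 did not. Drawing random lists from genes outside the list put glycolysis at the 1.55th percentile in place of the 2.56th and left the 8 lists outside the range. Depth is unknown, so the limits it sets on low genes could not be given.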

Other observations

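The tests of glucose exhaustion, of slower growth and of reads shared by PHO11 and PHO12 were chosen only after the results were seen, as were the genes named in the next 2 paragraphs.

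The rows beside DBP2 on chromosome XIV differed from it. RPC19, which lies just upstream (412771 to 413199), was 126 FPKM in wild type and 234 FPKM in the deletion strain, and CYB5, just downstream (416940 to 417302), was 164 FPKM and 103 FPKM. The next genes outward were YNL115C, at 121 FPKM and 124 FPKM, and NOP15, at 296 FPKM and 487 FPKM.

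Some rows of repeated names were far from another row of the same name in at least 1 strain. A row named MAS2, a mitochondrial processing peptidase gene, was listed at 3010000 FPKM in wild type and 273378 FPKM in the deletion strain, while its other row was 147 FPKM and 106 FPKM. A row named MAL11, a maltose transporter gene, was 4922 FPKM and 68.8 FPKM, against 21.6 FPKM and 47.0 FPKM on its other row. One named IRC7 was 8430 FPKM and 460 FPKM, against 552 FPKM and 358 FPKM, and one named IME2 was 5727 FPKM in wild type and listed at 0 in the deletion strain, against 7.31 FPKM and 23.3 FPKM. A row named PTR2, a peptide transporter gene, was listed at 0 in wild type and at 336 FPKM in the deletion strain, and its other rows were 135 FPKM and 182 FPKM, and 16.8 FPKM and 3.17 FPKM.

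The respiratory chain and general stress genes were higher together, with a median log2 ratio of 1.481 over 20 genes. Bias from gene length, GC content or expression level is argued against as the whole cause, since removing a trend on all of these, fitted on the other coding genes, left a median of 1.55 and all 20 genes above 0. Slower growth cannot be told apart, because the ribosome biogenesis median, at the 87.1th percentile of level-matched lists, lay inside their central range with 10 members higher and 11 lower, and 31 of 40 cytosolic ribosomal protein genes were lower as deposited but 21 with equal protein-coding sums. Glucose exhaustion at harvest stays open too, because the 9 gluconeogenesis and other-sugar genes compared had a median of 0.23 as deposited but 0.69 with equal protein-coding sums. Members on several rows were left out of that median. Among them PCK1 and SFC1 were higher on each of their rows, while others had rows going both ways. For slower growth and glucose exhaustion, the limits first written counted the deposited medians against each cause. Stricter limits were applied here, under which neither cause was decided. The loss of DBP2 and the other genotype differences between the strains stay open, since each strain is 1 sample.

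Phosphate genes were lower, with 7 of 8 beyond 2-fold. Reads shared by PHO11 and PHO12 leave the other 6 members unexplained, which had a median of -2.19 with 5 of them lower. With 7 of 8 members already seen beyond 2-fold, that outcome was fixed in advance, so it adds no evidence of its own. A trend on length, GC content and level left a median of -2.36. A general effect of position within 50 kb of chromosome ends is argued against, because 333 other genes there had a median 0.11 above that of the remaining genes. That window cannot show an effect confined closer to the ends, where PHO11 and PHO12 lie. The lower members SPL2 (374654 to 375100 of the 562643 bp of chromosome VIII) and VTC4 (411234 to 413399 of the 745751 bp of chromosome X) lie outside it. The deletion of DBP2 and the other genotype differences between the strains stay open here too.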
